A study of Homo sapiens with 3 samples.

How the data were processed

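Total RNA, extracted with TRIzol from 3 human ES cell lines grown on irradiated mouse embryonic fibroblast feeders with serum replacement and FGF2, was labelled with Cy3 for Illumina whole-genome expression arrays, per the labels' protocols. The labels put H9, BG03 and ES01 in 1 group, with 1 array per line; each line is a separate culture, so the spread over lines holds line, culture and array differences together.

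In the deposited values, each of 47293 probes has an intensity on each array. Its values are on a linear scale, and 33.8%, 32.8% and 26.3% of them are below 0 in H9, BG03 and ES01, so background had been subtracted; the column medians are 3.5, 3.5 and 4.4. The software used by the authors, and any scaling between arrays, are not given in the sources used here. Set against the bead means at the same ranks (500 to 5000), the table rose by 0.873, 0.974 and 0.920 units per unit of bead mean, so that a scaling that differed between arrays is possible and its form stays unknown. The deposited bead files give 1 green intensity per bead, with a red column that is 0 throughout, per the file headers and values. They hold bead codes that no table used here links to genes, so gene results come from the value table and bead files serve for technical error only.

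Genes were named through the platform annotation: 18468 probes have 1 gene symbol, 0 have several and 28825 are unnamed here. Of the named probes, 18451 were found by gene ID in the reference table (assembly GRCh38.p14, used for names, chromosomes and gene lengths only). Of 16225 genes, 32 (Y-linked, XIST and TSIX) were left out, leaving 16193. All probes except 4 bacterial control probes were quantile-normalized with limma 3.58.1 in R 4.3.3 (with version 1.17.8 of data.table). Background on each array was the 95th percentile of 215 olfactory receptor probes, 11.2, 12.6 and 13.3 units for H9, BG03 and ES01. For the 1610 genes with several probes the probe with the highest mean was used. For 633 genes, 2 probes were above background in some line. Counted per line, 35 cases differed at least 2-fold from the mean of the others, and a gene could count in more than 1 line. The second probe went the same way in 27 cases. Cases were picked by size at the first probe, which by itself favours smaller sizes at the second. The sizes were smaller: for H9, BG03 and ES01 the median log2 difference was 1.24, 1.15 and 1.32 at the first probe and 0.42, 0.93 and 0.27 in that direction at the second, so a 2-fold difference at 1 probe is often not 2-fold at another. Values under background were set to the threshold before log2 was taken, and differences used genes above background in at least 1 line.

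Lists were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 16 lists (462 of 508 listed symbols measured, repeats counted). The variance of each gene over the 3 lines was tested against the variance of genes of like intensity with limma's squeezed variances and an F-test. With 1 array per line no test between lines exists: genes differing at least 2-fold were counted, and list medians were placed among 10000 random lists matched on expression in 10 groups. Beads over 3 median absolute deviations from their type's median were left out (0.526% to 0.612% of beads). Of 48925 bead types, 5636 (11.5%) differed past bead error between H9 and BG03, 7218 (14.8%) between H9 and ES01 and 6273 (12.8%) between BG03 and ES01; this compares arrays, not lines.

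The lists, tests and most alternatives were fixed before the data were examined. So was the rule for named genes: the first 6 measured members of each list, any list member differing at least 2-fold between 2 lines, the 8 named genes per line with the largest difference from the mean of the others, and genes past the variance test. Genes with placeholder names were left out of the per-line choice. The plan adjusted the variance test over all tested genes and held no adjustment over single lists. Histone and protocadherin genes, and the G1/S genes, were chosen after values had been seen.

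The steps were tested on simulated data or on random draws from the measured values. For 11001 simulated genes with 200 changed in 1 line, the variance test recovered 0 at 4-fold and at 16-fold with the spread fitted to these arrays, and 126 (63.0%) and 195 (97.5%) with a more even spread between genes (50 prior degrees of freedom). Of 100 lists of 30 genes drawn at random from the measured ES01 and H9 differences, 3 fell outside the random range. With 0.3 added to every member, 100 of 100 fell above it. Such draws check the calculation and not how lists of genes regulated together behave. Alternatives covered the normalization, the background threshold and set, the probe rule, the floor, the filter on dim genes, the prior, the fold threshold and leaving out each line. Bead summaries and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.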

Results

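Gene expression was measured in 3 undifferentiated human embryonic stem (ES) cell lines, H9 (replicate 1), BG03 (replicate 2) and ES01 (replicate 3), with 1 Illumina bead array per line. The lines form 1 group. The study set human ES cells against mouse ES cells and epiblast stem cells; the mouse samples are not analysed here, so the comparisons are between kinds of gene within the human cells and between the 3 lines. Each array carried between 2089034 and 2102778 beads, with a median of 41 to 43 beads per bead type in each of its 2 files. For bead types brighter than 200 units the median standard error of the log2 mean over beads was 0.04 to 0.05. The number of arrays, 1 per line, limits the precision of every difference between lines. Intensities are given after quantile normalization in the order H9, BG03, ES01, and SDs are over the 3 lines on the log2 scale (n = 3).

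Most genes above background in any line were above it in all 3. Of 16193 genes, 9694 (59.9%) were above background in all 3 lines, 1308 in 1 or 2 lines and 5191 in none. Across the 11002 genes above background in at least 1 line, Pearson's r of log2 values was 0.984 between H9 and BG03, 0.978 between H9 and ES01 and 0.983 between BG03 and ES01. These are correlations across genes, which are not independent replicates; the spread of gene levels alone makes them high, and no second array of a line shows what to expect, so they do not measure how alike the lines are. The median absolute log2 difference was 0.19, 0.24 and 0.21 for the same pairs.

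Which kinds of gene human ES cells express was asked with 16 gene lists. Genes of the pluripotent state were mostly above background. LIN28A, an RNA-binding protein of pluripotent cells, had intensities of 5466, 5837 and 6489 (log2 SD 0.12), and DNMT3B, a de novo DNA methyltransferase, 6715, 7558 and 9013 (log2 SD 0.21). The core transcription factor POU5F1 measured 269.6, 287 and 195 (log2 SD 0.30), NANOG 130.1, 123 and 127 (log2 SD 0.04), and GDF3 475, 621 and 618 (log2 SD 0.22). SOX2, another core factor, was read by 1 probe that was not above background in any line. Whether that probe reads the transcript was not checked, so this does not show that SOX2 is absent. No other probe was checked in this way, so the same holds for every gene named below as not above background. Of 40 measured pluripotency genes, 35 were above background in all 3 lines, against 59.8% of other genes (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over the 16 lists, adjusted p = 6.9e-04).

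Activin, Nodal and FGF signalling genes were also mostly present, with 30 of 33 above background in all lines (Fisher's exact test, adjusted p = 4.7e-04). The Nodal antagonists LEFTY1 (10809, 14074 and 11243, log2 SD 0.21) and LEFTY2 (2727, 4287 and 3692, log2 SD 0.33) and the ligand NODAL (407, 503 and 909, log2 SD 0.60) were above background in every line. INHBA (16.5, 38.9 and 53.8) and INHBE (105.6, 57.6 and 78.5) were above it in every line. INHBB, an activin subunit like INHBA, passed it in ES01 alone, but only just (13.267 against a threshold of 13.257). In H9 it lay just under (11.15 against 11.21), so this is no sign of a difference between lines. Cell cycle genes were above background for 36 of 39 (adjusted p = 7.5e-05), including the cyclins CCNA2, CCNB1, CCNB2, CCND1, CCND2 and CCND3. Glycolysis genes were above it for 20 of 20 (adjusted p = 2.1e-04), among them HK1, HK2, GPI, PFKL, PFKM and PFKP. Chromatin regulators reached 26 of 29 (adjusted p = 0.00188), with DNMT1 at 2635, 3241 and 2544 and EZH2, the Polycomb methyltransferase, at 145, 166 and 193; DNMT3A was dim at 19.8, 23.5 and 24.2. TET1 measured 121, 108 and 113, and DNMT3L was above background in H9 and BG03. The p53, stress and apoptosis list reached 25 of 30 (adjusted p = 0.0149), with PMAIP1 at 1715, 1407 and 1128, while MDM2 was not above background in any line and BBC3 was above it in BG03 and ES01. These are two-sided Fisher's exact tests over genes, which are not independent, and genes such as GDF3 and DNMT3B stand in more than 1 list.

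Genes of differentiated lineages were less often above background. Neuroectoderm genes reached 5 of 31 (Fisher's exact test, adjusted p = 1.3e-05): SOX1, NEUROG1, NEUROG2 and NEUROG3 were not above background in any line, the eye and brain factor PAX6 was above it in BG03 and ES01, and the intermediate filament gene NES in all 3 (70.9, 99.2 and 107). Genes of mesoderm, blood, heart and muscle reached 8 of 31 (adjusted p = 4.9e-04), with MESP1, TBX6 and CDH5 not above background and KDR, a receptor of vascular growth factor, at 60.6, 44.4 and 47.9. MESP2 passed the threshold in H9 alone. Germ cell genes reached 7 of 26 (adjusted p = 0.00188), with DDX4, SYCP3 and STRA8 not above background, DAZL above it in H9 and ES01, SYCP1 in ES01 and SYCP2 in BG03. Trophectoderm genes reached 8 of 24 (adjusted p = 0.0178), with CDX2, CGA, CGB3, ELF5 and GCM1 not above background and EOMES at 522, 393 and 467 (log2 SD 0.21).

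**Figure D1:**
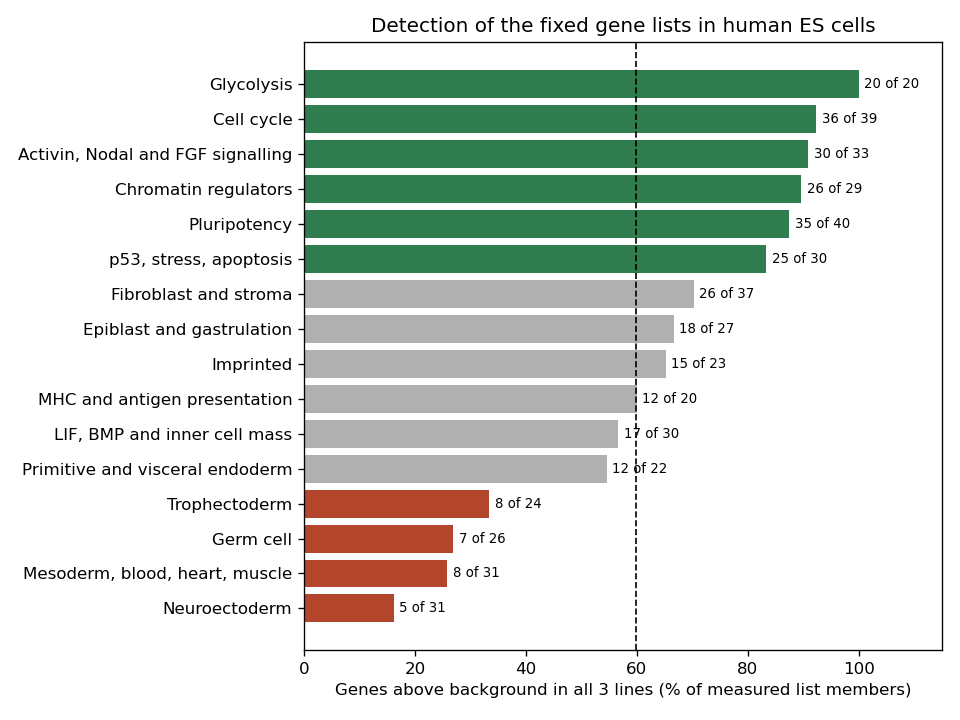
Share of the measured members of each gene list above background in all 3 lines (bars, percent), with the count beside each bar and the 59.9% of all genes as a dashed line. Green bars passed the two-sided Fisher's exact test above other genes (6 lists), red bars below (4 lists) and grey bars did not pass (6 lists).

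The remaining 6 lists did not pass the test. The LIF, BMP and inner cell mass list had 17 of 30 genes above background in all lines (adjusted p = 0.761): STAT3 was at 261, 255 and 254 (log2 SD 0.02) and JAK1 at 46.9, 59.1 and 59.4, while the LIF receptor subunits LIFR and IL6ST and the feedback inhibitor SOCS3 were not above background in any line, and LIF passed it in ES01 alone. LIFR is read by 1 probe and IL6ST by 2, not checked for reading their transcripts, so absence is not shown. Epiblast and gastrulation genes reached 18 of 27 (adjusted p = 0.744). OTX2 (784, 698 and 781), EOMES, FOXA2 (222, 185 and 195) and GSC (149, 108 and 151) were above background in all lines. The epiblast growth factor FGF5, read by 2 probes, and the primitive streak factor TBXT, read by 1, were above it in none. These probes were not checked either, so absence is not shown. Primitive and visceral endoderm genes reached 12 of 22 (adjusted p = 0.761), with GATA4 (68.7, 77.4 and 83.0), GATA6 (292, 314 and 366) and SOX17 (99.2, 92.4 and 105) above background in all lines and SOX7 in none. Fibroblast and stroma genes reached 26 of 37 (Fisher's exact test, adjusted p = 0.350). The collagen genes COL1A1, COL1A2, COL5A1, COL5A2 and COL6A1 were above background and COL3A1 was not. The lines grew on mouse fibroblast feeders, and whether feeder RNA adds to these signals was not tested. Imprinted genes reached 15 of 23 (adjusted p = 0.761), with MEST (1414, 884 and 1553), PEG10, DLK1 and PHLDA2 above background and IGF2 and PEG3 not. Antigen presentation genes reached 12 of 20 (adjusted p = 1), with B2M at 896, 889 and 799.5, HLA-C at 871, 1059 and 1074, HLA-E at 61.0, 67.5 and 68.6, HLA-G above background in BG03 and ES01 and HLA-F in none.

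**Figure D2:**
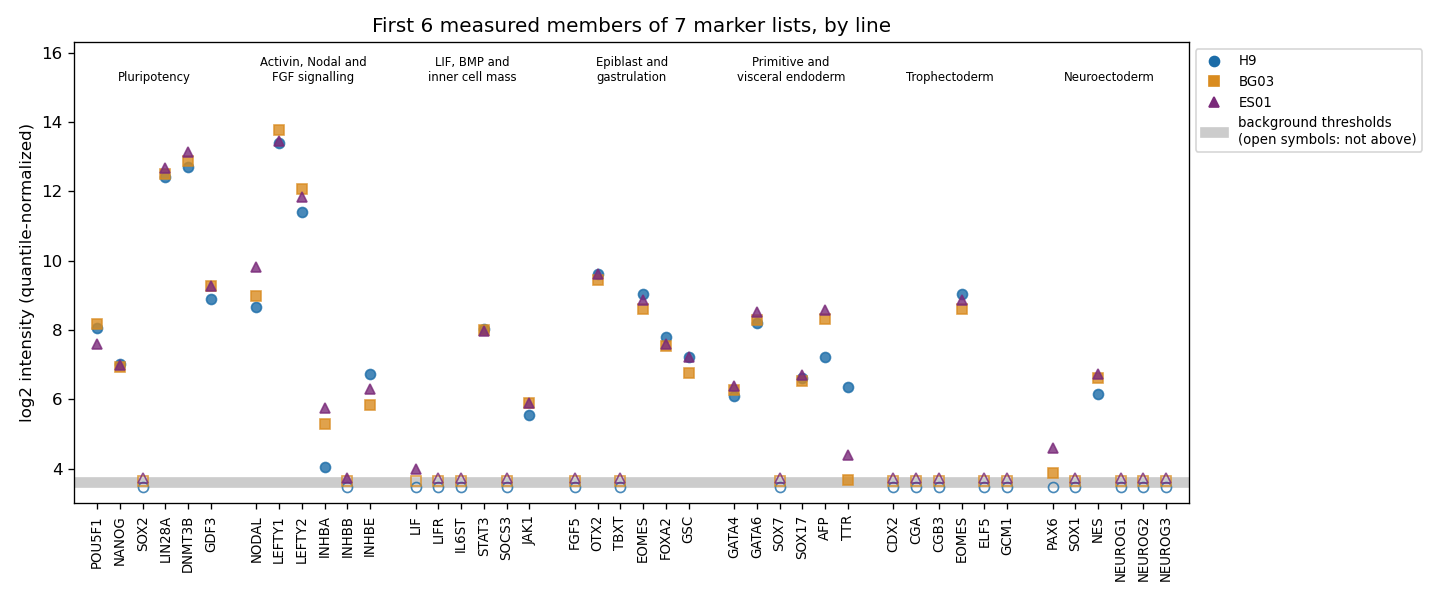
log2 intensity after quantile normalization (vertical axis) of the first 6 measured members of 7 lists in H9 (circles), BG03 (squares) and ES01 (triangles). Open symbols mark values not above background, drawn at each array's threshold (grey band); levels of different genes come from different probes and are not to be set against each other. SOX2, FGF5, TBXT and CDX2 are open in all 3 lines.

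No gene was shown to vary more between the lines than others of like intensity. The variance test with limma called 0 of 11002 genes at an adjusted p under 0.05, and the robust fit called 0. At an unadjusted p under 0.05 there were 521 genes, against 550.1 expected by chance. The spread was fitted to these same genes, which largely sets that number, so it says nothing on whether the lines differ. Adjusted over each list alone, without correction over the 16 lists, 1 gene passed: NNAT, an imprinted neuronal gene. Its adjusted p in limma's variance test was 0.0326 among the 17 tested imprinted genes and 0.979 over all 11002 genes. With 16 lists adjusted apart, 1 such pass may arise by chance. On simulated data with the spread fitted to these arrays, the test recovered 0 of 200 genes changed 4-fold or 16-fold in 1 line, so a count of 0 does not show that genes did not differ. Scaling the arrays to the same median gave 88 genes and leaving out ES01 gave 77.

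Differences between single lines have no replicate check and are given by size. ES01 stood at higher levels than H9 for several pluripotency and early embryo genes: GAL, a neuropeptide gene, measured 5847 against 2550, DPPA5 119.8 against 37.3, DPPA3 72.0 against 26.4 and NODAL 909 against 407. BG03 had the highest ZFP42, a zinc finger gene of pluripotent cells (780 against 364 in H9 and 247 in ES01), and H9 the highest UTF1 (717 against 307 and 342). VSNL1 was at 305, 229.9 and 549.6. A difference of at least 2-fold was found for 357 genes between H9 and BG03 (192 higher in BG03), 566 between H9 and ES01 (319 higher in ES01) and 413 between BG03 and ES01 (250 higher in ES01). Of all genes above background in at least 1 line these are 3.24%, 5.14% and 3.75%. The share higher in ES01 was 56.4% against H9 and 60.5% against BG03, and 21.1% and 18.1% with the arrays scaled to the same median, where the median difference of all genes was -0.27 and -0.34 (0.01 and -0.01 after quantile normalization). The medians that this scaling sets equal, 3.5, 3.5 and 4.4 units as deposited, lie under the background thresholds of 11.2 to 13.3. Its factor therefore rests on probes not above background. With a floor of 50 units the counts were 126, 226 and 165.

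For H9, the largest differences from the mean log2 value of the other 2 lines were mostly lower values. HENMT1, a small RNA methyltransferase, was not above background in H9 and was at 301 and 276 in BG03 and ES01, at least 25.7-fold lower in H9. PSMD5, a proteasome assembly factor, was at least 19.4-fold lower, QPCT at least 10.8-fold and ZBED10P at least 10.6-fold. CSRP1 was 13.4-fold lower (54.2 against 586 and 907), ERVMER34-1, an endogenous retroviral envelope gene, 10.7-fold and GNA14 9.90-fold, and MOCOS was 11.95-fold higher (282 against 26.7 and 20.9). In BG03, the protocadherin PCDHB5 was 16.6-fold lower (19.3 against 229 and 449.9), HLA-B 6.56-fold lower (29.0 against 176 and 205), ARMCX5 at least 14.4-fold, WDR90 at least 7.58-fold and CTHRC1 at least 6.71-fold lower. PCDH15, not above background in H9 and ES01, was at least 5.29-fold higher in BG03. In ES01, TCEAL5 was 11.8-fold higher (218 against 15.9 and 21.2), NNAT at least 11.1-fold, PCDHB3 at least 8.26-fold and COX7A1 at least 6.89-fold, while ACTN3 was 7.73-fold lower (23.0 against 231 and 136) and ZNF680 and ZNF558 at least 7.40-fold and 7.29-fold lower. Bounds take the array's background threshold for a value not above it. Each of these genes is read by 1 probe except NNAT and PCDH15, with 2; HLA-B differs in sequence between people, and 1 probe need not read every form alike.

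Other list members differing at least 2-fold lay in every list except the cell cycle list. In the Activin, Nodal and FGF list these were INHBA, FGF8 and the FGF feedback phosphatase DUSP6 (95.4, 103 and 218). In the LIF, BMP and inner cell mass list they were KLF5 (27.0, 23.6 and 76.7), TCL1A (22.5, 25.4 and 84.4), TCL1B, FBXO15, GBX2, TBX3 and the BMP target ID2 (616, 259 and 403.5). AFP was lower in H9 (148 against 322 and 383), whereas TTR (81.5, 12.8 and 21.0), APOA1 and APOA2 were highest there. Among stress genes, the cell cycle inhibitor CDKN1A was lowest in H9 (99.5, 219 and 393), as were GADD45A and GADD45B, and DDIT4 was highest (369.5, 100.2 and 57.7); FOSB, JUN and IER3 were lowest in ES01. Of 37 measured fibroblast list members, 12 differed at least 2-fold. They included ANXA1 (86.1, 198 and 626), CCN2 (2848, 4611 and 5851), S100A6, LGALS1 (799, 349 and 917), ACTA2, IGFBP7, TWIST1, LUM, DCN and LOX. The rest of the 12 were among the collagen genes named above. The receptor gene TEK (29.4, 48.1 and 162), TNNI3, ACTC1 and HAND1 differed in the mesoderm and muscle list, OLIG2, DCX, ZIC1 and PAX6 in the neuroectoderm list, DND1, TDRD1 and TEX14 in the germ cell list, and DKK1 in the epiblast list. SLC2A1, a glucose transporter (77.6, 90.3 and 225), PDK1, SMARCA5, CBX7, DNMT3L, L3MBTL1 and HLA-DPA1 were the others.

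As lists, signalling and early embryo genes stood higher in ES01. The median log2 difference between ES01 and H9 was 0.36 for Activin, Nodal and FGF genes (23 of 32 higher), 0.34 for LIF, BMP and inner cell mass genes (13 of 21), 0.32 for epiblast and gastrulation genes (14 of 20), 0.20 for pluripotency genes (23 of 36) and 0.43 for mesoderm, blood, heart and muscle genes (8 of 10). Floors differed between arrays, so these counts include genes above background in neither line, such as PCSK6 (2.83 in H9 and 6.8 in ES01). With 1 floor for the arrays the LIF, BMP and inner cell mass median was 0.25, and the other medians stayed as given. Primitive and visceral endoderm genes (-0.31) and glycolysis genes (-0.16) lay lower in ES01. The endoderm median was inside the random range in 4 of 10 alternatives: -0.14 with the 99th percentile background and in genes above background in all lines, -0.18 with the second background set and 0.16 without the filter on dim genes. Against BG03, ES01 stood higher for the first 4 of these lists (0.24, 0.51, 0.23 and 0.08; the 0.51 was 0.14, inside the random range, with the 99th percentile background), for fibroblast and stroma genes (0.31) and for germ cell genes (0.37). BG03 lay below H9 for epiblast genes (-0.12) and glycolysis genes (-0.09). These 15 of 48 medians lay outside the central 95% of 10000 random lists matched on expression. If lists behaved as random draws of genes, 2.4 would be expected outside. Genes of a list may be regulated together, which such draws do not copy. Pairs are not independent, since they share arrays, and both ES01 pairs rest on the same ES01 array. The medians describe these arrays and carry no p. Of the 15, 5 stayed outside in all 10 alternatives (Activin, Nodal and FGF genes in both ES01 pairs, pluripotency genes against H9, epiblast and fibroblast genes between ES01 and BG03), but the fibroblast median fell to 0.13 with the 99th percentile background and 0.12 without the filter. Random lists not matched on expression ended the calls for glycolysis genes in both pairs, pluripotency genes between ES01 and BG03 and epiblast genes between BG03 and H9, and the second background set that for mesoderm genes (0.26). Same-median scaling moves ES01 by -0.33 against the values as deposited for 11001 of 11002 genes alike, so it leaves places among random lists as they were. The medians against H9 fell to 0.03 for Activin, Nodal and FGF genes, 0.03 for LIF, BMP and inner cell mass genes, 0.01 for epiblast genes and 0.10 for mesoderm genes, and grew to -0.61 for endoderm and -0.41 for glycolysis genes. Against BG03 they fell to 0.19 for LIF, BMP and inner cell mass genes, 0.00 for fibroblast genes and 0.07 for germ cell genes. Medians turned for pluripotency genes (-0.09 against H9 and -0.26 against BG03) and, against BG03, for Activin, Nodal and FGF genes (-0.11) and epiblast genes (-0.09). With 50 added in place of the floor, LIF, BMP and inner cell mass genes were at 0.17 against H9 and 0.27 against BG03, epiblast, mesoderm and endoderm genes at 0.19, 0.19 and -0.17 against H9, and fibroblast genes at 0.14 against BG03; as deposited, glycolysis genes were at -0.08 between ES01 and H9 and -0.02 between BG03 and H9, and epiblast genes at -0.07 between BG03 and H9.

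**Figure D3:**
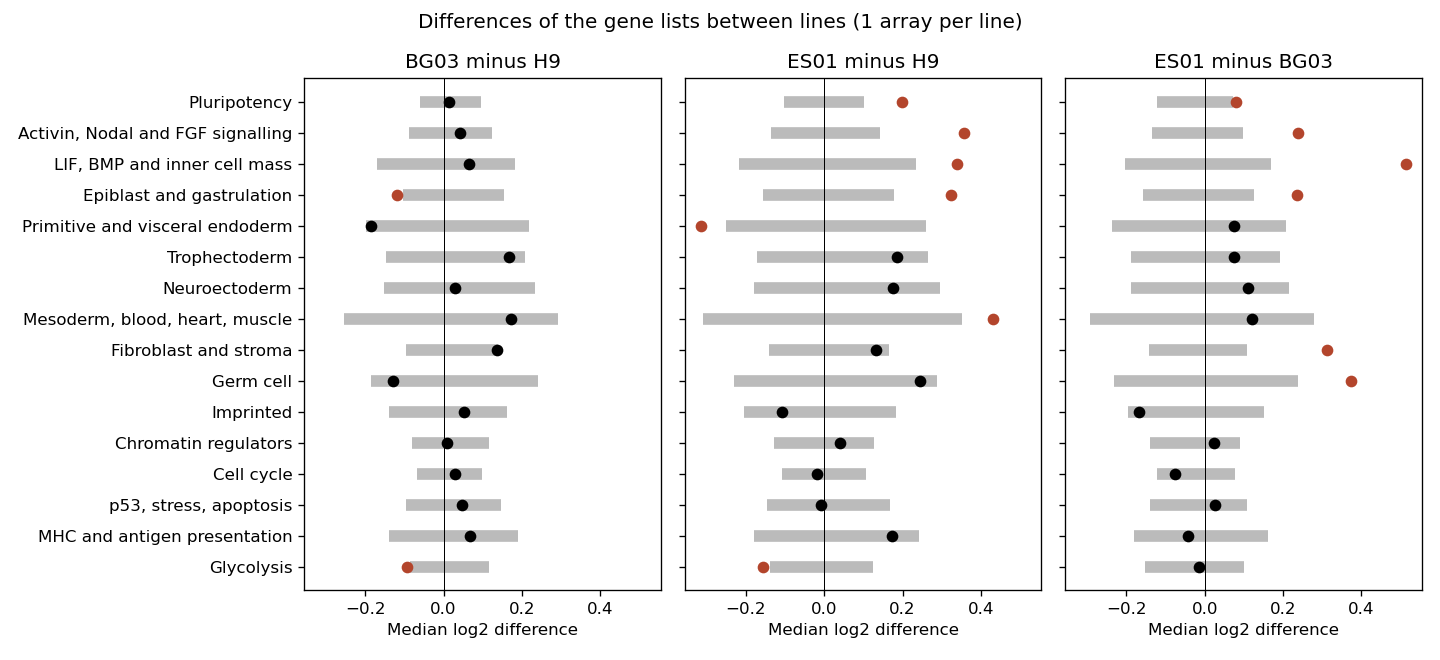
Median log2 difference of each list's genes between a pair of lines (points) with the central 95% of 10000 random lists of the same size matched on expression (grey bars), 1 array per line. Red points, 15 of 48, lie outside the bar; the Activin, Nodal and FGF list lies at 0.36 between ES01 and H9 and at 0.24 between ES01 and BG03. Under same-median scaling the median of all genes was -0.27 and -0.34 in those pairs.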

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

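The counts here were chosen after the data were seen. Probes with no listed gene are outside every comparison of the report, and many carried signal. Of 7623 such probes with GI identifiers, 1824 (23.9%) were above background in all 3 lines, and of 11622 with Hs identifiers 739 (6.36%), against 2.79% of the olfactory receptor probes. Of 9576 probes with hmm identifiers 253 (2.64%) were above it, no more often than olfactory receptor probes, although the brightest, hmm31879-S, measured 3850, 3495 and 3936 in H9, BG03 and ES01.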

How the results depend on the processing

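The floor of 50 units, the single floor for all arrays and the histone and protocadherin settings were chosen after the data were seen. Detected genes (8591 to 9925, and 9850 to 9947 leaving out a line), the 10 list detection calls, array correlations, chromosome and bead counts stayed on their side of their limits under every alternative run for them. Genes past the variance test numbered 88 with same-median scaling (cause not tested), 402 without the filter on dim genes, where undetected genes sit at each array's floor and have a fixed small spread by construction, and 0 to 77 leaving out 1 line (77 without ES01, 4 without BG03, 0 without H9; the cause was not tested). The 2-fold counts for H9 and BG03, H9 and ES01, and BG03 and ES01 were 1306, 1797 and 1479 at 1.5-fold and 88, 143 and 87 at 3-fold, by construction, and 71, 116 and 88 with 50 added in place of the floor and 126, 226 and 165 with a floor of 50, both of which shrink differences of dim genes. The 99th percentile background gave 199 and 263 for H9 and BG03 and for BG03 and ES01. List medians outside the random range were 8 without the filter, against 15; there calls ended between ES01 and H9 for the LIF, BMP and inner cell mass, epiblast and mesoderm lists (0.24 each) and endoderm (0.16), between ES01 and BG03 for the LIF, BMP and inner cell mass, pluripotency and germ cell lists (0.075 each), and between BG03 and H9 for epiblast (0.14). The values 0.24 and 0.075 are the difference of the floors by construction. The LIF, BMP and inner cell mass median between ES01 and BG03 was 0.14 at the 99th percentile background, inside the random range, and the epiblast median between BG03 and H9 -0.09 with 50 added. With 1 floor for the arrays the counts were 331, 533 and 404, and 16 list medians. Of the list medians under the alternatives, 443 kept their side, 16 lost it, 19 gained it and 2 (mesoderm and germ cell without the filter) came to the middle of random lists. No paired analysis was possible because the series has 1 group. Signal over background limits genes near 11.2 to 13.3 units.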

Other observations

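The histone, protocadherin and G1/S gene sets and all tests on them were chosen after the data were seen, as were the tests of normalization, fibroblast genes, arrays and chromosome gain below; the tests of the length trends, the chromosome 6 neighbourhood and the poly(A) tail were chosen before their own values were seen. In all, 10 explanation tests were run.

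Histone genes whose transcription is tied to DNA replication stood lowest in H9. Over 36 such genes above background in at least 1 line, the median log2 difference was 0.55 between ES01 and H9 (35 higher, 1 lower) and 0.53 between BG03 and H9 (32 higher, 4 lower). The counts include genes that differ only through the unequal floors. H4C9 counts as higher in ES01, at 11.1 and not above background there, against 11.4 in H9. H3C12 and H4C5 count as higher in BG03, though not above background there or in H9. With 1 floor for the arrays both medians were 0.49. H1-2 measured 247, 659 and 750 in H9, BG03 and ES01, H2BC5 82.8, 132 and 310, and H4C14 36.7, 81.4 and 137. Between ES01 and BG03 the median was 0.21, and it was -0.10 under same-median scaling, where the median of all genes was -0.34, 0.07 with the 99th percentile background, 0.10 with 50 added and 0.075 without the filter, in the middle of random lists. With 50 added in place of the floor the H9 differences were 0.28 and 0.22, the first was 0.22 with same-median scaling and the second 0.31 with the 99th percentile background, all above random lists. Without the filter on dim genes they were 0.24 and 0.17, in the middle of random lists, where the median is the difference of the floors by construction. Protocadherin beta genes, cell adhesion genes of a clustered family, stood higher in ES01 than in BG03: over 10 genes the median was 0.66 (9 higher), and 0.37 with same-median scaling, 0.41 with 50 added, 1.09 over 6 genes with the 99th percentile background and 0.16 over 16 genes without the filter, above random lists in each. The set holds PCDHB5 and PCDHB3, already named above for their large differences, and no median without them was computed. Between ES01 and H9 the median was 0.33, inside the random range (-0.34 to 0.39), and 0.01 with same-median scaling. Between BG03 and H9 it was -0.33, below random lists, but inside their range with the 99th percentile background (-0.20), with 1 floor for the arrays (-0.27) and without the filter (0.16).

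For the histone pattern, the 8 other genes lying within the chromosome 6 cluster had a median of -0.16 between ES01 and H9, which argues against a change of that whole neighbourhood. More cells in S phase stays open. It was first read from the cell cycle list, whose median was -0.0174 (inside the random range) and was taken to exclude it. That list mixes phases that can move apart, so its G1/S genes were tested next. For 13 of the 15 listed, those above background in at least 1 line, the median was 0.13. It lay at percentile 90.7 of random lists, above 0 but inside the range. Capture of RNA without a poly(A) tail, which mRNAs of this class are taken here to lack, may also differ between preparations. Whether each gene of the set lacks tailed transcripts was not checked, and the explanation need not reach any gene that makes them. The 8 replication-independent histone genes, whose mRNAs carry a tail, had a median of -0.0891, as this explanation predicts. A real difference between lines in these genes predicts that value too, and with 1 array per line it was not tested.

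For the higher signalling and early embryo lists in ES01 than in H9, the median of the 99 pooled genes was 0.26 with values as deposited, above random lists (-0.02 to 0.13), which argues against quantile normalization as the whole cause; same-median scaling moves genes alike and decides nothing, and the scaling of the deposited values stays open. The median was 0.21 after a trend on gene length was taken off. Fibroblast genes, 26 of 37 of which were above background in all lines, had a median of 0.13 between ES01 and H9, inside the random range. Of these, 19 were higher and 14 lower, with 6 at least 2-fold higher and 0 lower. The median lay above the range in 4 of 10 alternatives: 0.21 as deposited, -0.12 with same-median scaling, 0.18 with the mean over probes and 0.24 without the filter. Same-median scaling only repeats the place of the values as deposited, and 0.24 is the difference of the floors by construction. With 1 floor for the arrays the median was 0.09, inside the range. These values do not decide whether H9 held more fibroblast-like cells, so that stays open. A median at or above 0 was first taken to exclude more fibroblast-like cells in H9. Such a list may hold genes the lines express themselves, and mouse feeder RNA is read by these human probes only in part. An array or labelling difference cannot be told apart from a line difference with 1 array per line.

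Small shifts of whole autosomes were seen, with 14 of 66 medians outside random gene sets. The largest was 0.0802 (chromosome 13 in ES01), far under the 0.58 of a gain from 2 to 3 copies in all cells, which argues against such a gain; a gain in few cells stays open. Across 22 autosomes the ES01 shift went with median gene length (Spearman's rho = 0.547, permutation p = 0.00937; Pearson's r = 0.610, permutation p = 0.00245; r = 0.575 without the 2 farthest), consistent with a length trend as a candidate source. Other sources were not tested, and this was the only relation of its kind computed.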
